A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

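RNA was measured by 3'-end sequencing, which reads the ends of polyadenylated transcripts next to the poly(A) tail, in 4 cultures of budding yeast (Saccharomyces cerevisiae). Per the labels, 2 were wild type and 2 had the genotype swr1 htz1, which names both genes, and all were grown in rich glucose medium at 30 °C to log phase. SWR1 encodes the ATPase of the complex that places the histone variant H2A.Z in nucleosomes, and HTZ1 encodes H2A.Z itself. The kind and extent of the mutations are not given in the sources used here. The design text calls the samples biological replicates.

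The values are raw read counts per gene as the authors deposited them, in a sense and an antisense row for each gene, per the file headers. CASAVA 1.8 and Bowtie 0.12.7 are named in the submitters' processing notes, with no role given there. The counting tool, the genome build, the annotation, the window in which reads were counted and the choice of genes are not given in the sources used here. Each file lists the same 3914 genes, against 6021 protein-coding genes in the R64 reference annotation. Of the listed names, 3912 matched an R64 locus tag and 2 did not. R64 was used for gene symbols, for neighbouring genes and for distances along a chromosome. Because the authors' build is not named, no coordinates are printed. The file holds no rows for unassigned reads, so every row entered the library totals.

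Sense counts were tested with edgeR 4.0.16 in R 4.3.3. The steps were TMM normalization, the filterByExpr filter (3840 genes tested, 74 left out), robust dispersion estimation and the robust quasi-likelihood F test of genotype, with all 4 libraries in one fit and no covariate. That fit has 2 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of its F statistic. CPM values (read counts scaled to a common library total) were computed from the deposited counts with TMM-scaled library sizes. DESeq2 1.42.0 and limma 3.58.1 (voom) were run as alternatives on the same genes.

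Before the data were examined, 40 gene lists were fixed from textbook pathways, complexes, cell type markers and chromosome position. Of these, 30 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30. Camera with an estimated correlation, camera on ranks and fry, a rotation test of the list's own members, were alternatives. The rule for named genes, also fixed in advance, took SWR1 and HTZ1, the 12 genes furthest apart in each direction among called genes with at least 10 CPM in the higher group and no overlap between groups, up to 4 members by adjusted p of each list that camera called, and every measured histone gene and neighbour of SWR1 or HTZ1. The part of the rule that needed called genes selected 0 genes. In its place the same rule was applied to genes at unadjusted p below 0.05, a choice made after their values were seen. The antisense rows were tested in the same way (1826 genes passed the filter), which was also decided after the files were seen.

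The test was run on simulated data: 5 simulated data sets of the swr1 htz1 against wild type comparison were drawn for the 3840 tested genes from their measured means, dispersions and library sizes, with 200 changed genes in each. edgeR called 1.2% of the genes changed 2-fold, 24.8% of those changed 4-fold, 82% of those changed 8-fold and 94.8% of those changed 16-fold. DESeq2 called 10.8%, 62.8%, 96.4% and 99.2% of them. These shares hold with 200 changed genes per data set, which eases the adjusted threshold, and would be lower with fewer changed genes. Unchanged genes made up 6.97% of all edgeR calls and 20.6% of all DESeq2 calls on the planted and unchanged genes. A planted list of 17 genes raised 2-fold was called by camera in 5 of 5 data sets, and 0 of 145 unchanged lists were. Genes were drawn independently of each other, while the estimated correlation within a real list reached 0.47 (hexose transport). The simulation therefore cannot show how often camera wrongly calls lists whose members vary together.

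The other settings were RLE, upper-quartile and total-count scaling, 2 other count filters, non-robust and newer quasi-likelihood fits, an adjusted p threshold of 0.01, the replicate number as a block, each library left out in turn, other distances from the chromosome end, and the fit without genes near the largest count. No sample was left out of the main comparison.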

Results

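The series compared transcript levels in yeast labelled swr1 htz1 with wild-type yeast, with 2 libraries per genotype. The sense counts summed to 13970701 and 13023973 reads in wild type (replicates 1 and 2) and to 12951812 and 14773382 in swr1 htz1. Between 3893 and 3899 of the 3914 listed genes had at least 1 sense read, and the median gene had 661 to 773 reads. A gene with 0 reads could still lie at up to 0.203 to 0.232 CPM (3 reads) depending on the library, counting error only. The antisense counts summed to 142678 to 199521 reads per library.

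The genes named in the genotype were examined first. SWR1 (YDR334W) was measured at 64.3 ± 22.1 CPM (SD, n = 2) in wild type and 1.66 ± 0.23 CPM in swr1 htz1, with 670 and 1041 reads against 24 and 22. The fold change was -5.27 on the log2 scale (SE 0.47), or 38.7-fold lower. HTZ1 (YOL012C) was measured at 39.9 ± 6.6 CPM in wild type and 19.1 ± 6.0 CPM in the mutant, a log2 fold change of -1.06 (SE 0.39). Its sense reads were 485 and 581 in wild type and 308 and 219 in swr1 htz1, while its antisense reads were 95 and 20 against 0 and 0. Where the HTZ1 reads lie relative to any deleted segment is not given, so they do not test that part of the genotype label. By edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p over all genes was 0.247 for SWR1 and 0.849 for HTZ1, and both genes passed when adjusted over the list alone. On sense reads DESeq2 called SWR1 (adjusted p 6.2e-19) but not HTZ1 (adjusted p 0.45). On antisense reads HTZ1 was called by DESeq2 (adjusted p 0.00134) but not by edgeR (adjusted p 0.641). Of the 4 genes next to SWR1 and HTZ1, 3 were measured, and none passed the edgeR test. RQC1, a ribosome quality control gene beside SWR1, had a log2 fold change of 0.59 (SE 0.34). MSN5, a nuclear transport receptor on its other side, had 0.03 (SE 0.35), and PLB3, a phospholipase gene beside HTZ1, had 0.76 (SE 0.42).

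The genome-wide comparison asked which genes differ between the strain labelled swr1 htz1 and wild type; the series title speaks of removing H2A.Z. No gene out of 3840 was called by edgeR, whose smallest adjusted p was 0.247. SWR1, at 38.7-fold lower, was not called either, so the lack of calls does not exclude large changes of single genes. At unadjusted p below 0.05 edgeR listed 223 genes, 117 higher and 106 lower in swr1 htz1, where 192 would be listed by chance. The libraries of the 2 genotypes did not overlap for 1324 genes (34.5%), where chance gives 33.3%. limma voom also called 0 genes (205 at unadjusted p below 0.05). DESeq2 called 83 genes, 55 higher and 28 lower, each with non-overlapping libraries and each at least 2-fold apart. In the simulated data 20.6% of DESeq2's calls were unchanged genes, 175 over 5 data sets. That share holds with 200 planted genes per data set and would be higher with fewer changed genes, so it is not an error rate for the 83 calls. Split across genotypes instead, with 1 library of each genotype on either side, the same libraries gave 48 and 57 DESeq2 calls and 174 and 176 genes at unadjusted p below 0.05.

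The genes lying furthest below wild type, among those with at least 10 CPM in the higher group and chosen after their values were seen, came from several processes. After SWR1 came TIF2 (YJL138C), one of a near-identical pair of genes for the translation factor eIF4A, with 11317 ± 7411 CPM in wild type and 456 ± 22 in swr1 htz1 (log2 fold change -4.63, SE 0.64). Its near-identical copy TIF1 had 57 and 52 reads in wild type and 61 and 81 in the mutant, so the division of reads between the pair is uncertain, and TIF2's 215584 reads in wild-type replicate 2 lay within 1% of the largest count in that library, which 7 genes shared to that precision, so that value may be capped and the fold understated. UBP14 (YBR058C), a ubiquitin protease gene, had 18.2 ± 8.7 CPM against 0.79 ± 0.06 (log2 fold change -4.51, SE 0.58). MCM21 (YDR318W), which encodes a kinetochore protein, had 129 ± 25 CPM against 11.1 ± 5.5 (-3.54, SE 0.49). SYO1, an import factor for ribosomal proteins, was 9.94-fold lower, with 6315 and 14471 reads in wild type and 1270 and 909 in the mutant. ATP20, a subunit of the mitochondrial ATP synthase, was 9.60-fold lower (8098 and 19855 reads against 1340 and 1747). MRPS28, a mitochondrial ribosomal protein gene, was 9.10-fold lower, with 3820 and 1359 reads in wild type and 228 and 364 in the mutant. SBE2, a gene of bud wall growth, was 8.32-fold lower (5261 and 12957 reads against 1077 and 1236). CSI1, of the COP9 signalosome, was 9.20-fold lower, with 394 and 428 reads in wild type and 17 and 79 in the mutant. GIC1, an effector of the polarity GTPase Cdc42, was 8.22-fold lower, with 997 and 164 reads against 62 and 83, so its fold rests largely on wild-type replicate 1. The uncharacterised YPR084W had 246 and 4916 reads in wild type and 150 and 143 in the mutant. MAM1, of the meiotic monopolin complex, had 36 and 278 reads against 11 and 26. Of these 12 genes, SWR1 included, DESeq2 called all except MAM1, and edgeR called none (adjusted p 0.247 to 0.849).

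The genes lying furthest above wild type, chosen in the same way, were of mixed function. YCK2 (YNL154C), a casein kinase I of the plasma membrane, had 64.7 ± 39.2 CPM in wild type and 513 ± 71 in swr1 htz1 (log2 fold change 2.99, SE 0.55). BST1 (YFL025C), which remodels GPI anchors in the endoplasmic reticulum, had 1062 ± 542 CPM against 8260 ± 3619 (2.96, SE 0.59). PPH3 (YDR075W), the catalytic subunit of a phosphatase that acts on phosphorylated histone H2A, had 53.6 ± 25 CPM against 327 ± 42 (2.61, SE 0.44). RRN9 (YMR270C), an activator of ribosomal RNA gene transcription, had 50.9 ± 21.6 CPM against 304 ± 1 (2.58, SE 0.40). ICS2 was 6.55-fold higher, but its wild-type replicates lay apart (136 and 384 reads, against 1603 and 2008 in the mutant). The small heat shock protein gene HSP42 was 6.61-fold higher and FET5, which encodes a multicopper oxidase, 7.27-fold higher, but their mutant replicates lay at 257 and 751 and at 1429 and 350 reads. The mutant replicates also lay far apart for ADD37 (285 and 1571 reads), ELA1 (811 and 170), BDP1 (712 and 3890), DUF1 (2172 and 549) and AFI1 (656 and 2892). DESeq2 called 11 of these 12 genes, all except BDP1, and edgeR called none (adjusted p 0.265 to 0.849).

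**Figure D1:**
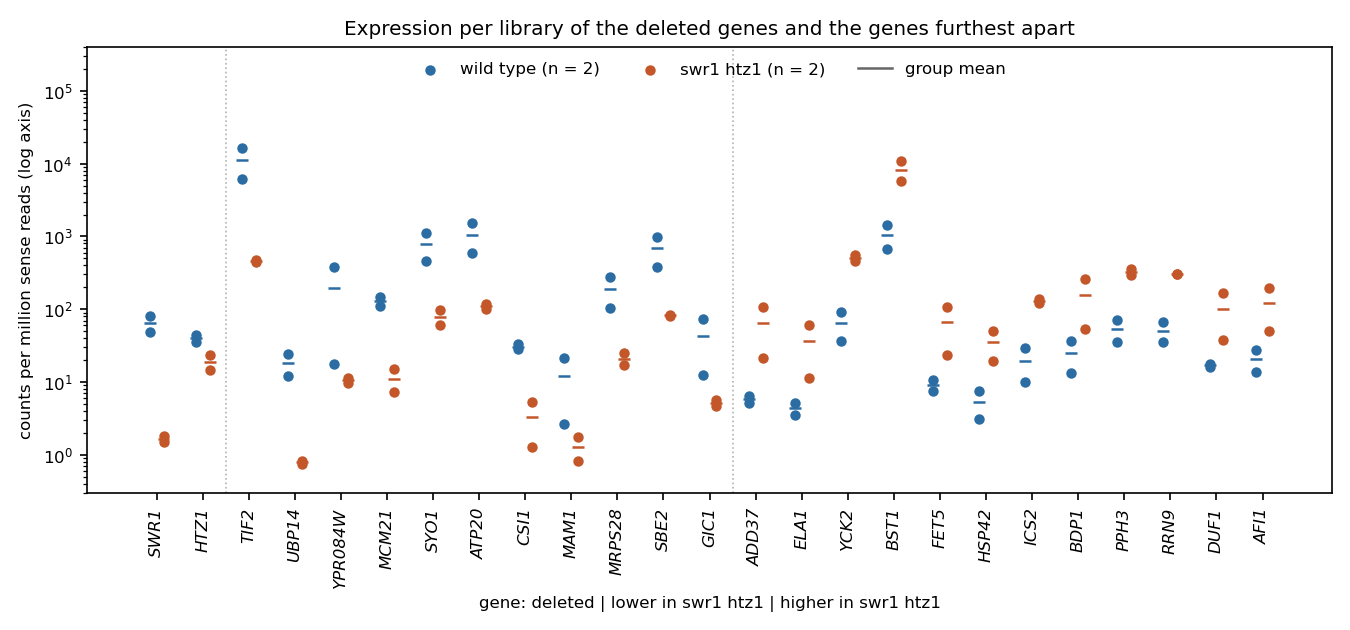
CPM of sense reads (log axis) in each library for SWR1 and HTZ1, 11 genes lower in swr1 htz1 and 12 genes higher; points are libraries and short lines group means. The libraries of the genotypes do not overlap for any gene shown, which the selection required of all but that pair, and no gene passed edgeR's adjusted threshold; SWR1 lies at 64.3 CPM in wild type and 1.66 CPM in the mutant.

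At camera's preset correlation 2 of the 30 tested lists were called, galactose use with lower values in swr1 htz1 and cell wall construction with higher values (adjusted p 0.0138 for each). Neither was called by camera with an estimated correlation (adjusted p = 0.97 for each, unadjusted p = 0.0765 for galactose and 0.0847 for cell wall). The estimated correlations were -0.042 for galactose and 0.015 for cell wall, against the preset 0.01, so correlation between members accounts for little of the rise in p. That setting uses the 2 residual degrees of freedom of the fit, which leaves it little power. Neither list was called by fry (adjusted p = 0.32 for each). Of the 6 tested galactose genes, 5 had lower values and 1 a higher value, and the median log2 fold change was -1.36 (-0.74 without wild-type replicate 2). GAL2 (YLR081W), the galactose permease gene, had 5.37 ± 2.49 CPM in wild type and 0.64 ± 0.15 in the mutant (-3.05, SE 0.60). GAL4 (YPL248C), the activator of the pathway, had 88 and 91 reads against 18 and 33 (-1.89, SE 0.47). PGM2, a phosphoglucomutase gene that is also on the stress list, had a log2 fold change of -1.93 (SE 0.79) and GAL10, the epimerase gene, of -0.83 (SE 0.50). GAL2, GAL4 and GAL10 lay below 10 CPM in every library of these glucose-grown cultures. GAL4 had more antisense than sense reads in every library (211 and 149 antisense in wild type, 368 and 387 in the mutant). GAL80, the repressor gene, lay at -0.07 (SE 0.27), and GAL1, the galactokinase gene, lay the other way at 1.07 (SE 0.86), with 237 and 1325 reads in wild type and 1689 and 1786 in the mutant. edgeR called 0 members over all genes, with GAL2 and GAL4 at unadjusted p below 0.05, and both passed adjusted over the list alone. DESeq2 called GAL2, and limma voom called 0.

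Of the 17 tested genes of the cell wall list, 15 had higher values and 2 lower, with a median log2 fold change of 0.39, or 1.31-fold. The higher genes include MLP1 (YKR095W, 0.38, SE 0.49), which encodes a nuclear pore protein and not a cell wall protein. It was matched to the list by its symbol and entered the list tests. GSC2 (YGR032W), a glucan synthase gene, had 38.2 ± 3.7 CPM in wild type and 103 ± 30 in swr1 htz1 (1.43, SE 0.33). CHS3, a chitin synthase gene, had 130 ± 12 CPM against 253 ± 93 (0.96, SE 0.36). PST1, a cell wall protein gene, had 33.4 ± 7.9 CPM against 65.3 ± 13.2 (0.97, SE 0.34), and PRM5 had 33.6 ± 4.9 CPM against 59.9 ± 2.5 (0.83, SE 0.29). CHS1, another chitin synthase gene, lay lower at -1.37 (SE 0.71). edgeR called 0 cell wall genes over all genes and 0 adjusted over the list alone, with 5 higher at unadjusted p below 0.05, and DESeq2 and limma voom called 0. The galactose call was lost without wild-type replicate 2 (adjusted p 0.496, median -0.74), swr1 htz1 replicate 1 (0.147, median -1.02) or swr1 htz1 replicate 2 (0.0823, median -1.66). The cell wall call was lost without wild-type replicate 1 (median 0.55), wild-type replicate 2 (median 0.49) or swr1 htz1 replicate 2 (median 0.44). In those fits its median stayed above the 0.39 of all 4 libraries, but without swr1 htz1 replicate 1 it was 0.29. Regrouping the libraries by replicate number instead of genotype gave 2 called lists, ribosome biogenesis and protein folding (smallest camera adjusted p 0.0025). The other regrouping across genotypes gave 0 (smallest adjusted p 0.0732).

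**Figure D2:**
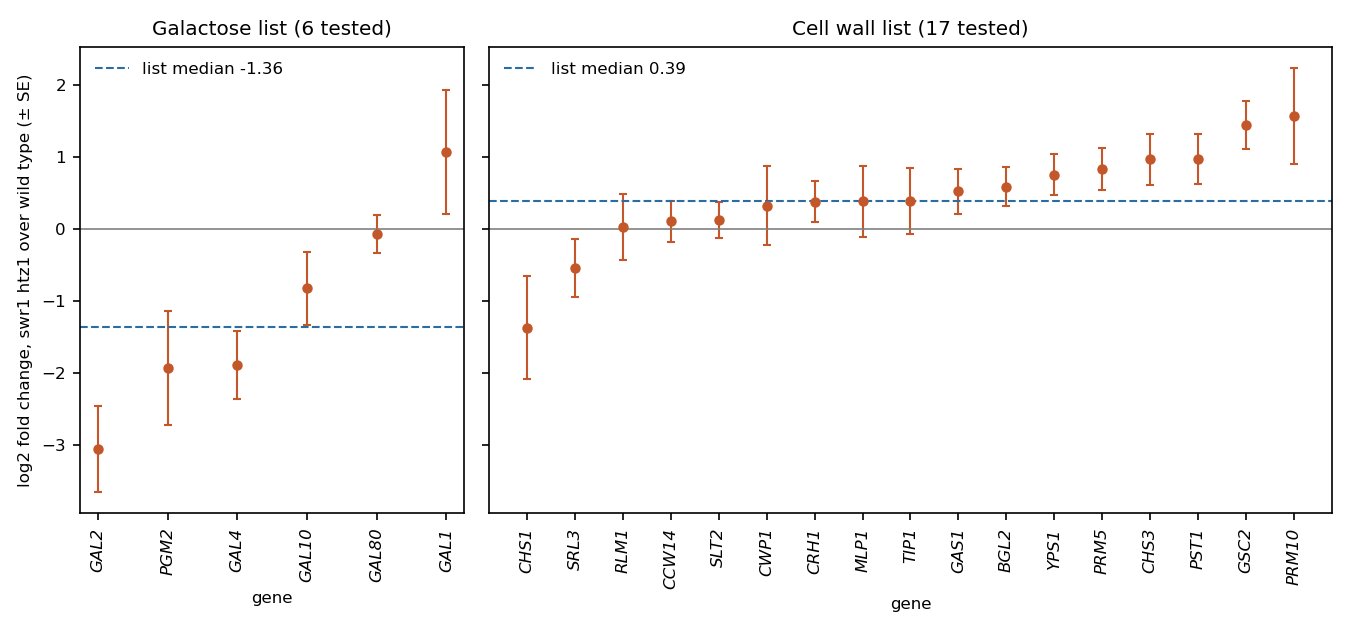
Log2 fold change (swr1 htz1 over wild type) with its standard error for each tested gene of the galactose and cell wall lists; the dashed line is the list median. GAL1 lies opposite to the galactose median of -1.36, and 15 of 17 genes of the cell wall list lie above 0, among them the nuclear pore gene MLP1.

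Other chromatin genes showed no difference between genotypes that passed a test. Histone genes had log2 fold changes of -0.42 (SE 0.53) for HTA1, 0.74 (SE 0.48) for HTB1, 0.06 (SE 0.47) for HHT1, -0.41 (SE 0.29) for HHF1 and 0.42 (SE 0.59) for HHO1. HTA1, HTB1, HHT1 and HHF1 have close copies elsewhere in the genome, which can share reads. The remaining 11 measured members of the SWR1 complex had a median log2 fold change of 0.07 (7 above 0, 4 below; camera adjusted p 0.939). The 5 measured members of INO80, another remodeller of H2A.Z nucleosomes, had a median of 0.08 (adjusted p 0.807), and 12 silencing genes one of 0.16 (adjusted p 0.897). The 19 tested genes within 20 kb of a chromosome end, of 246 annotated in R64, had a median of 0.00 against 0.01 for the other genes (camera adjusted p 0.807). Of these, 1 (5.26%) was at unadjusted p below 0.05, against 5.81% elsewhere (Fisher's exact test, two-sided, p = 1). None of the genes of the silent mating loci, the PAU family or the YRF1 helicases was analysed here.

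Housekeeping and stress lists did not pass either. The 26 general stress genes had a median log2 fold change of 0.42, with 20 above 0 (camera adjusted p 0.123), and the 16 genes of the iron list one of 0.47 (adjusted p 0.134). The 17 protein folding genes had a median of 0.25 and the 88 cytosolic ribosomal protein genes one of -0.09 (adjusted p 0.332 for each). Medians were -0.05 for 55 ribosome biogenesis genes (adjusted p 0.807), -0.12 for 9 phosphate genes (0.807), 0.13 for 19 cell cycle genes (0.874), -0.02 for 11 spindle and checkpoint genes (0.332) and 0.10 for 14 DNA damage genes (0.939). The median of the 15 meiosis and sporulation genes was -0.58, while their mean was 0.02 (adjusted p 0.939). Of 6 strain marker genes 2 had higher values and 4 lower, with a median of -0.08 and a mean of 0.17 (adjusted p 0.807). The member that DESeq2 called was CAN1, the arginine permease gene, with 197 and 187 reads in wild type and 449 and 614 in the mutant (log2 fold change 1.40, SE 0.32; adjusted p 0.0461 by DESeq2 and 0.507 by edgeR).

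Differences between replicates of one genotype were similar in size to those between genotypes. Between the wild-type replicates 707 of 3840 genes (18.4%) differed over 2-fold and 198 (5.16%) over 4-fold, and between the swr1 htz1 replicates 723 (18.8%) and 240 (6.25%). Across the 4 pairings of a mutant with a wild-type library, 16.5% to 21.8% of genes differed over 2-fold. The correlation of log2 CPM across genes, which are not independent replicates, was 0.928 within each genotype and 0.917 to 0.928 between genotypes. The biological coefficient of variation estimated by edgeR was 0.418.

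**Figure D3:**
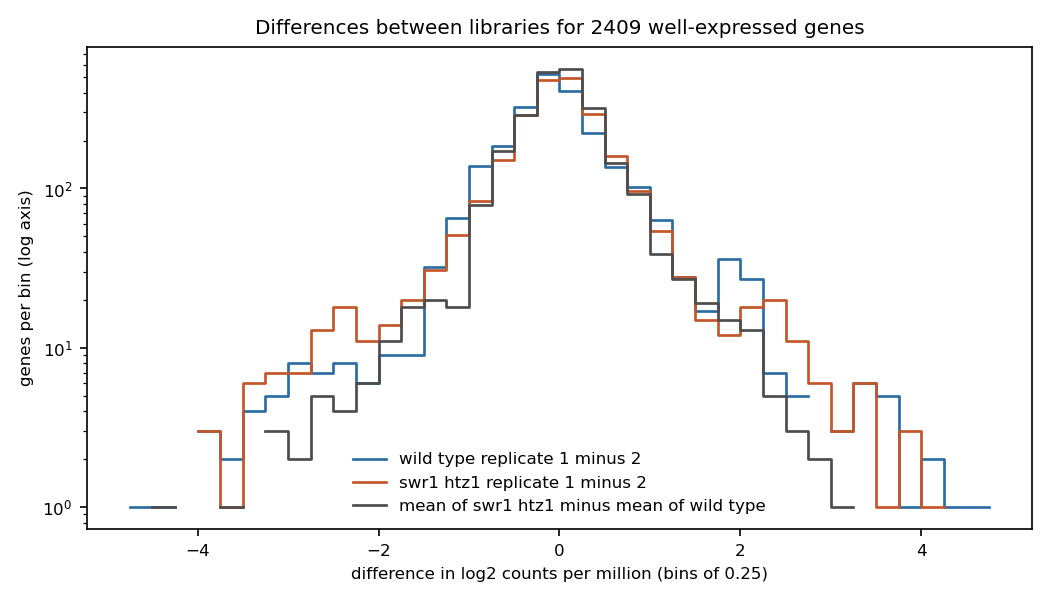
Number of genes (log axis) by difference in log2 CPM, in bins of 0.25, for 2409 genes with a mean log2 CPM above 5. The lines compare replicates of wild type, replicates of swr1 htz1, and the genotype means, and since the last averages a pair of libraries on each side it is expected to be narrower; differences between replicates reach beyond 4-fold (2 on this axis) on both sides.

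Antisense reads, counted separately per gene, were compared between the strain labelled swr1 htz1 and wild type. Because the counting window is not given, they may include reads from the transcript of a neighbouring gene. Some genes had more antisense than sense reads, such as PDR3 in wild type (1290 and 1204 antisense, 508 and 349 sense). There were 11.8 ± 1.1 antisense reads per 1000 sense reads in wild type and 13.2 ± 0.4 in swr1 htz1 (SD, n = 2 each). Both mutant libraries lay above both wild-type libraries, and the exact permutation test (two-sided) gave p = 0.333, the smallest that 2 against 2 allows. edgeR called 0 of 1826 genes (smallest adjusted p 0.641), with 123 at unadjusted p below 0.05 where 91.3 would be listed by chance. limma voom called 0 (95 at unadjusted p below 0.05). DESeq2 called 17 genes, 8 higher and 9 lower. Among these, antisense reads of FOL2, a folate synthesis gene, were 2 and 1 in wild type and 48 and 46 in swr1 htz1. Those of KIP3, a kinesin gene, were 5 and 2 against 128 and 48, and those of SWC5, a subunit of the SWR1 complex, 9 and 4 against 50 and 134. Antisense reads of AXL2, a bud site gene, were 110 and 132 against 13 and 18, and those of LSC2, of the citric acid cycle, 448 and 121 against 32 and 36. Regrouped across genotypes, the antisense counts gave 2 and 15 DESeq2 calls, and 77 and 116 genes at unadjusted p below 0.05 by edgeR.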

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

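The antisense tests and the fit without genes near the largest count were chosen only after the result was seen. The count of called genes stayed at 0 under 15 of 16 alternatives. Among these, an adjusted p threshold of 0.01 could not call a gene where 0.05 called none. Genes changed at least 2-fold are a subset of the called genes, so their count was 0 under the same 15. DESeq2 called 83, all of them at least 2-fold, with a SWR1 log2 fold change of -5.28. The count at unadjusted p below 0.05 ranged from 187 to 306 against 223. The replicate number as a block gave 0 called genes, 187 at unadjusted p below 0.05 and the same 2 lists. The labels tie the numbers to no shared day or batch, and the numbers were not used as pairs in the main fit. Deviations of same-numbered libraries were not correlated across all genes (r = 0.0018). Regrouping by number nevertheless called the ribosome biogenesis and protein folding lists (smallest camera adjusted p 0.0025), so a state shared by same-numbered libraries is not excluded. The SWR1 value ranged from -5.59 to -4.87 and the HTZ1 value from -1.44 to -0.78. The subtelomeric difference kept its side of the threshold under 18 alternatives (-0.07 to 0.09). Among these, an adjusted p threshold of 0.01 could not change the outcome. Leaving out the COS, PAU and YRF1 families left the difference the same, so it was no test either. Within 10 kb only 2 genes were tested, too few for camera. The number of called lists was 2 in the main test, 1 (cell wall) with limma voom or camera on ranks, and 0 with an estimated correlation, with fry or at an adjusted p of 0.01. The adjusted p ranged from 0.0042 to 0.97 for galactose and from 0.0068 to 0.97 for cell wall. Leaving out each library, where the lone library is assumed to vary like the other group, gave 0 to 4 lists: 1 without wild-type replicate 1, 0 without wild-type replicate 2 or swr1 htz1 replicate 2, and 4 without swr1 htz1 replicate 1 (cell wall, general stress, protein folding and ribosome biogenesis). With the stricter count filter galactose had too few members left, and the stress list was called beside cell wall. Of the antisense genes DESeq2, run only with its own scaling, called 17, and edgeR called 0 with either antisense or sense library sizes. The cause of the gap between DESeq2 and the other tools was not tested on the real counts. The median log2 difference of all genes lay between -0.03 and 0.03 under the TMM, RLE, upper-quartile and total-count scalings.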

Other observations

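Each test in this part was chosen after the result was seen, except the correlation of sense with antisense differences. Genes specific to alpha cells had more reads than genes specific to a cells in all 4 libraries. STE3, the receptor gene expressed in alpha cells, had 8392 and 2176 sense reads in wild type and 4551 and 3311 in swr1 htz1, and SAG1, the alpha agglutinin gene, had 4443 and 2264 against 7872 and 8134. STE2, the receptor gene expressed in a cells, had 109 and 80 against 60 and 105, and STE6, the a-factor exporter gene, 51 and 8 against 7 and 53. Among general stress genes the members went both ways: TSL1, of trehalose synthesis, had 146 and 65 reads against 318 and 440, GPH1, of glycogen breakdown, 445 and 402 against 802 and 1561, and GRE1 53 and 37 against 8 and 5.

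A few genes, named after their values were seen, had fewer reads from both strands in the mutant. The uncharacterised YFL012W had 99 and 135 sense reads in wild type and 0 and 2 in swr1 htz1, and 340 and 383 antisense reads against 15 and 1. PEX9, of peroxisomal import, had 45 and 45 sense reads against 4 and 4, and 380 and 336 antisense reads against 100 and 136. GAL2 had 98 and 47 sense reads against 7 and 11, and 274 and 26 antisense reads against 1 and 5. In all, 8 genes of 1786 were at unadjusted p below 0.05 on both strands, where 7.46 would be by chance; 5 were lower on both (these 3, HTZ1 and TOS8), 1 was higher on both and 2 went opposite ways. The hypothesis that antisense transcription might lower its gene across the set was tested by the Spearman correlation of sense with antisense log2 differences. It was -0.00125 across 1786 genes (permutation p = 0.956 with 10000 resamples), between the values of the other splits (0.0119 and -0.0171). Differences between genotypes were similar in size to those between replicates, so a weak correlation was likely whether or not the hypothesis holds. The correlation therefore gave no sign of such an effect but does not decide the question.

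Replicates lay far apart even for deeply counted genes: of the genes with a mean of at least 1000 reads, 5.25% differed over 4-fold between the wild-type replicates, which argues against low depth as the cause. In addition 6 to 8 genes per library lay within 1% of its largest count (216803, 215587, 180323 and 250869 reads), and the next gene lay at 141501 to 164536. Whether the 15 genes concerned were capped is not known; they are few beside the 707 genes that differed over 2-fold between the wild-type replicates. A change in chromosome number was argued against too, since the largest median difference of any chromosome was 0.123 (log2). Gene-specific differences in priming, amplification or counting windows between libraries remain a candidate explanation that these counts cannot test, and no other biological explanation was tested.

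Genotype separated somewhat more genes than the other ways of dividing the libraries. There are 3 such splits, too few for a share under 0.05, and 1 of the 3, the real one, reached 223 genes at unadjusted p below 0.05; the highest other gave 176.

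Genes near SWR1 stood out among those at low p: within 50 kb (R64 distances), 7 of 33 tested genes (21.2%) were at unadjusted p below 0.05 besides SWR1, against 5.81% of all genes, and 0.646% of 3714 loci had a share as high. They were RAD34, SWA2, ASP1 and GPI8, with higher values, and MCM21, MRPS28 and SBE2, with lower values, and in the other splits the window held 1 such gene each. Around HTZ1 it was 4 of 37, a share above that of all genes but reached by 11.2% of loci, which leaves a like pattern there open, and with windows of 25 and 100 kb the SWR1 share was reached by 12.3% and 1.17% of loci. A window was centred on each gene, so windows of nearby loci overlap and can hold the same genes, SWR1 or HTZ1 included. The loci are therefore not independent, and these percentages are not p-values. A candidate explanation is a chromosome segment that came with the swr1 mutation when the strain was built, carrying sequence differences that alter expression or read mapping. The genes went both ways, the window was picked after the genes were seen, and no strain sequence was examined, so chance clustering and a local effect of the mutation remain open.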
